A study of Solanum lycopersicum x Solanum pennellii with 523 samples.

How the data were processed

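The series holds RNA-seq libraries of tomato fruit skin from a cross between cultivated tomato (Solanum lycopersicum) and its wild relative Solanum pennellii. It covers introgression lines (IL), which carry a defined wild segment in a cultivated background, and backcross inbred lines (BIL), which carry wild segments left after backcrossing. The labels give 523 libraries, 57 of IL and 466 of BIL, whose titles name 497 lines. In 26 lines (3 IL and 23 BIL) the titles end in a and b and mark 2 libraries of the line. Each IL title starts with a chromosome number, which set the group of the line. BIL titles name no chromosome, so the 443 BIL lines stayed 1 group and none was grouped by its reads.

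Reads were aligned with STAR 2.4.2a and counted with HTSeq, per the submitters' processing notes. The genome build, the annotation and the rule that assigned a read to a species are not given in the sources used here. Whole RNA was extracted with a tri-reagent protocol, and the library protocol is a patented high-throughput transcriptome method, per the labels' protocols. The authors deposited 3 tables of raw counts per locus and library, with no normalization. The tables named lyc and ind hold 34761 Solyc loci each, and the table named pen holds 44965 Sopen loci. From these names and values, lyc was read as counts assigned to S. lycopersicum, pen as counts assigned to S. pennellii and ind as counts that were not assigned to a species. Over libraries the median share of all counts was 68.86% in lyc, 27.55% in ind and 3.42% in pen. Nothing in the data used here pairs Sopen with Solyc loci, and the files do not pair loci with gene names.

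The tests were fixed before the data were examined. The planned total per gene, the sum of the 3 tables, needed paired loci and was not made. Expression therefore stands on the ind counts, and the sum of lyc and ind is the alternative. How far an allele change moves reads into or out of the ind table is not known here. That choice followed the first look at the tables. Library totals over the 3 tables ran from 315 to 16932111, and 436 of the 443 BIL lines and 51 of the 54 IL lines held at least 100000 counts. Counts of the 2 libraries of a line were summed, so the line is the replicate. Replicates of an IL group are different lines with different, partly overlapping wild segments. In the expression tests a p-value rests on a spread between lines that is pooled over all groups in the fit. That spread holds differences of genotype, plant and library. The p-value need not reflect the spread within the tested group, so a rise carried by few of its lines can have a small p-value.

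Expression is given in CPM, the counts of a locus over the library total, scaled to 1e+06. The wild read share is the pen count over the sum of pen and lyc counts, over all loci of a chromosome, taken from the 2 digits after Solyc or Sopen. For single lines its 95% interval is exact (Clopper-Pearson) and covers counting error only, since the deposited counts may contain copies of 1 molecule. The excess of a line on a chromosome is its share minus the median of IL lines labelled for another chromosome. Shares were compared by permutation tests with 100000 resamples, all two-sided, whose smallest possible p is 1e-05. The tests of gene sets against wild shares over BIL lines used 10000 permutations and were one-sided. Along the genome, pen counts of each line were scaled to CPM in 878 windows of 50 consecutive Sopen loci, with a pseudocount of 50 CPM, and a BIL line counted as raised in a window above 8 times the median of IL lines.

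Expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr at a minimum count of 10 and Benjamini-Hochberg adjustment at 0.05. IL against BIL used 6937 genes. The IL groups were fitted in 1 model of 54 lines and 8317 genes, and each group was set against the mean of the other 11. DESeq2 1.42.0 was an alternative. Totals of calls over the IL groups are given as percent of the tests made, with 1 test per gene and group (8280 on and 91524 off the labelled chromosome), since alternatives test different numbers of genes. Whether a total moved by over 1.5 times was read from the counts. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with the fry rotation test. The 9 lists, named ripening, carotenoid, flavonoid, cuticle, glycoalkaloid, volatile_sugar_acid, photosynthesis, defense and housekeeping, held 131 members, of which 118 have a locus in the files. Their symbols were tied to locus IDs from general knowledge, and no annotation here checks them. Photosynthesis stood for green tissue and cuticle for skin. Lists based on gene descriptions were not made, because no descriptions were used here.

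Named genes followed a fixed rule. Between IL and BIL these were the 10 largest rises and falls with mean CPM of at least 10. In each IL group these were a large rise and fall on and off the labelled chromosome, with mean CPM of at least 10 over IL lines. Other genes with larger called rises on the labelled chromosome lay in groups 1, 2, 4 and 9. List members past the threshold, the regulators and the 10 genes of highest repeatability complete the rule. Genes without a symbol are described by their place, and 4 of them by their ID. Printed CPM values leave out lines under 100000 counts.

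The deviation of a line is the median absolute difference of log2 CPM (prior count 1) from the median of IL lines of other groups. Repeatability is the intraclass correlation of log2 CPM over pairs of libraries of a line, with 10000 permutations. A regulator was set against the mean z-score of the other members of its list with at least 5 CPM, where the number of BIL lines with a count of it was no less than the number without, a limit set after the tables were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.

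Each procedure was tested on simulated data. Of 100 genes per fold size among 8393 genes, the edgeR fit recovered 6% at a 2-fold and 37% at a 4-fold change in the chromosome 6 group of 2 lines. It recovered 13% and 57% in the chromosome 8 group of 4 lines and 34% and 80% in the chromosome 9 group of 7 lines. For IL against BIL, among 7031 genes, it recovered 97% and 99%. Reads of a gene and of a near-identical copy or an antisense gene cannot be separated here, and this covers families of like genes such as the chlorophyll-binding and RBCS genes.

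Alternatives covered the normalization, the low-count filter, the test, single libraries in place of lines, lyc and ind counts summed, lines of low total, the comparison group, the threshold and each line left out in turn. After the data were seen, fits without lines under 100000 counts, without lines against their label, on the lyc table and on pairs with at least 50000 ind and lyc counts per library were added.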

Results

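RNA was counted in 523 libraries of manually peeled fruit skin from field-grown tomato at the breaker stage of ripening, about 44 days after anthesis. Plants stood in a randomized design at 4 per m2. The libraries belong to 497 lines, 54 of them IL and the rest BIL. Lines labelled for chromosomes 1 to 12 numbered 5, 5, 3, 4, 5, 2, 6, 4, 7, 4, 3 and 6. With columns joined by name across the tables, the total count per library had a median of 1215724 and a maximum of 16932111. The middle 50% ran from 900168 to 1667256, and 14 libraries held under 100000 counts. As lines, 3 IL (IL5-4, IL11-2 and IL12-3) and 7 BIL stayed under 100000 counts, and the smallest, IL12-3, had 76 ind counts. Line totals had a median of 1233216 in BIL, and among IL groups the median ran from 625124 in chromosome 11 to 2215998 in chromosome 9. The 10 most abundant loci took a median of 20.62% of ind counts.

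The first comparison asked whether each IL line carried wild transcripts on the chromosome in its name. Wild reads made up 20.64% ± 12.63 (SD, n = 54 lines) of species-assigned counts on the labelled chromosome. On the other 11 chromosomes together their share was 2.72% ± 0.88. The difference was 17.92 ± 12.89 percentage points and was positive in 51 of 54 lines (sign-flip permutation test, p = 1e-05, the smallest possible). In 46 lines the labelled chromosome had the highest excess of all 12. The highest labelled share among lines with at least 100000 counts was 53.48% on chromosome 7, and the chromosome 6 group, with 31.9% and 42.33% in its 2 lines, had the highest mean.

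**Figure D1:**
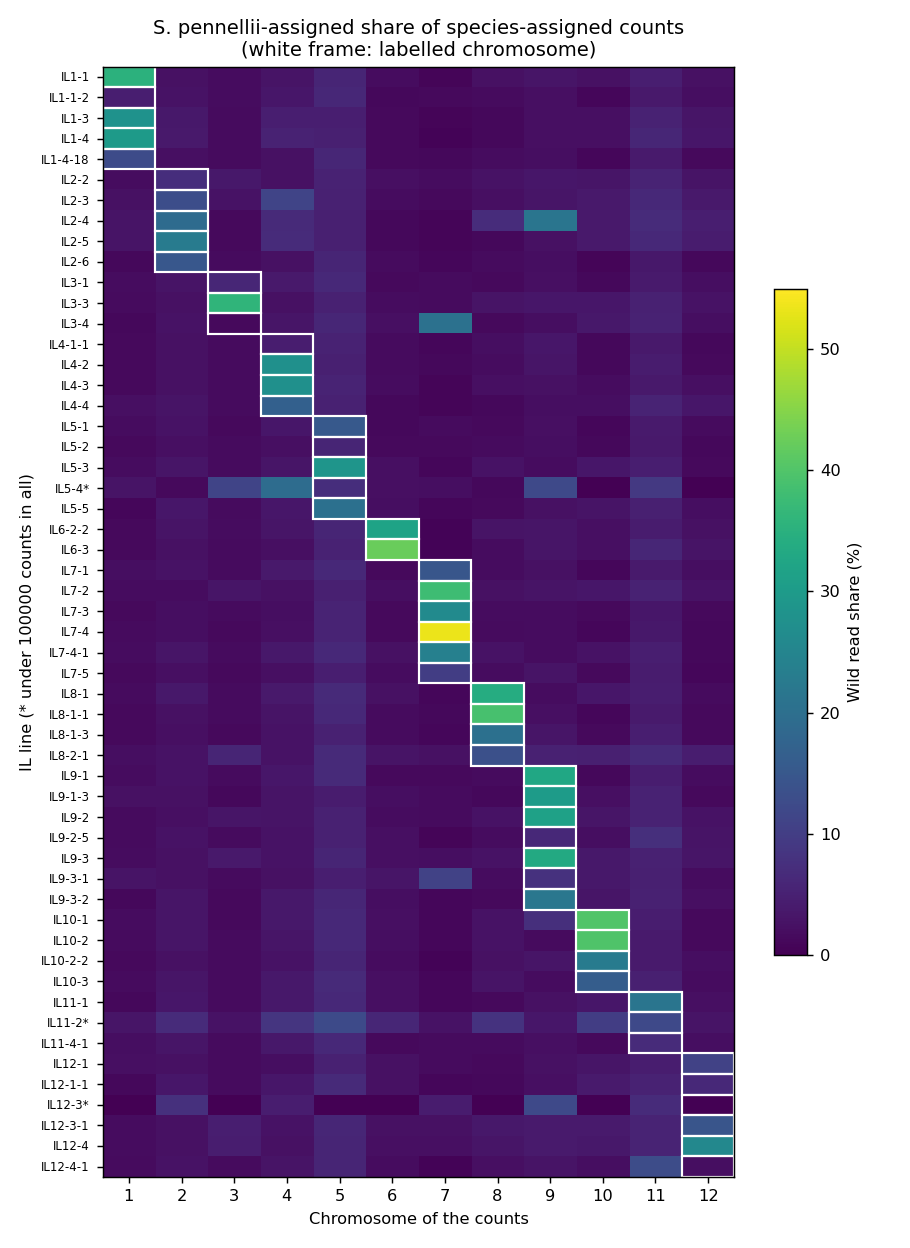
Wild read share (percent, colour) of each IL line (vertical axis) on each of the 12 chromosomes (horizontal axis), with the labelled chromosome framed in white and lines under 100000 counts starred. The framed cells average 20.64%, and in 51 of 54 lines the framed share exceeds that of the other 11 chromosomes pooled, while in some lines, such as IL3-4, another single cell is higher.

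Some lines went against their label. IL3-4 had 20.62% wild reads on chromosome 7 and 1.42% (95% exact interval 1.34 to 1.49) on chromosome 3. The line named IL12-4-1 had 12.85% on chromosome 11 and 1.99% (1.84 to 2.14) on chromosome 12. In IL9-3-1 chromosome 7 reached 10.75% and chromosome 9 held 7.93% (7.8 to 8.06), and in IL2-4 chromosome 9 reached 21.31% beside 19.25% (18.9 to 19.6) on chromosome 2. IL5-2 had no excess above 0.25 percentage points on any chromosome, with 5.66% (5.44 to 5.89) on chromosome 5 against a median of 5.67% in IL lines of other groups. Of the 2 libraries of IL2-3, library a had 16.22% on chromosome 4 and 2.34% (2.23 to 2.46) on chromosome 2. All these lines stayed in the group of their label.

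The 2 populations differed in the share of wild reads. This share includes the background that IL lines show on chromosomes they are not labelled for, so it is not the share of introgressed transcripts. The median background ran from 1.09% on chromosome 7 to 5.67% on chromosome 5. Wild reads made up 5.49% ± 2.70 (SD) in all BIL lines and 4.37% ± 1.41 (n = 54) in IL lines, so IL minus BIL was -1.12 percentage points (permutation test, p = 0.0026). The gap was smaller than the spread within either population, which ran from 1.7% to 14.93% in BIL and from 1.97% to 8.08% in IL lines.

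In BIL lines chromosome 11 carried the most wild transcripts. Its share was 13% ± 15.23 (SD over BIL lines with at least 100000 counts, which leaves out 7), against a median of 4.7% in IL lines labelled for another chromosome. On chromosome 11 a share over 50% was seen in 21 BIL lines, and the highest was 79.32%. The mean stood above that median by 8.3 percentage points on chromosome 11, by 4.24 on chromosome 10 (6.59% ± 11.52), by 4.16 on chromosome 5 (9.82% ± 10.39) and by 3.61 on chromosome 4 (6.53% ± 10.39). The smallest gaps were 1.28 points on chromosome 3 (2.86% ± 4.53) and 1.39 on chromosome 1 (3.08% ± 5.26). Along the genome, wild counts were raised in 64 BIL lines in the window from Sopen11g005010 to Sopen11g005500 and in 61 lines in the window before it. Of the windows raised in at least 40 lines, 7 lay on chromosome 11 and 1 on chromosome 10. These shares describe the population and were not tested.

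**Figure D2:**
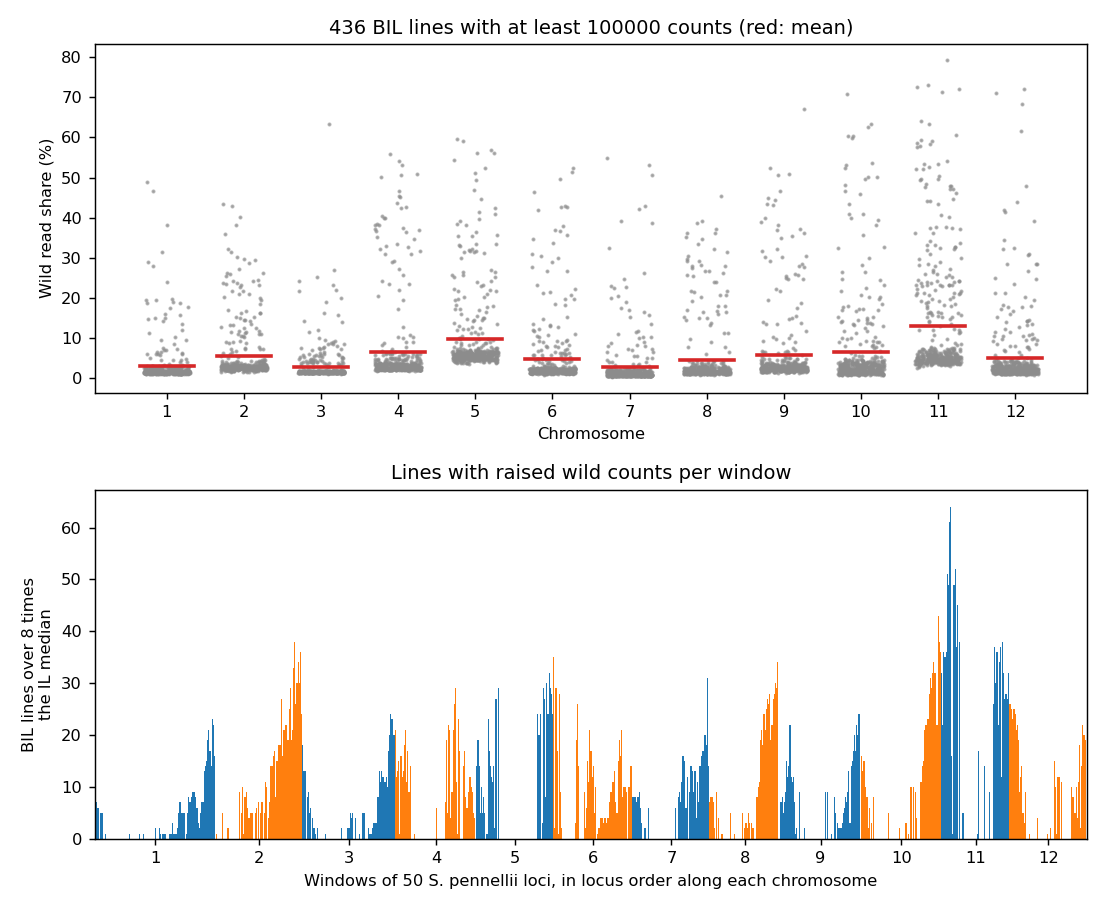
Top, wild read share (percent) per chromosome in BIL lines with at least 100000 counts, 1 point per line, with the mean as a red bar; bottom, number of BIL lines with raised wild counts in each window of 50 Sopen loci, in colours that alternate between chromosomes. Chromosome 11 has the highest mean, 13%, and the window with the most lines, 64.

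The next comparison asked which genes each labelled chromosome changed in the skin, by setting the lines of a group against the other IL groups. On the labelled chromosome 73 genes rose and 0 fell, with log2 fold changes from 0.75 to 7.20 and a median of 2.27. Several were near silent in other lines. Solyc08g006410 rose by 7.20 ± 0.46 (log2, SE; edgeR adjusted p = 7.41e-18) in the chromosome 8 group. It stood at 464.7 CPM in IL8-1-1, 284.3 in IL8-1-3 and 153.7 in IL8-1, at 0 in IL8-2-1, and at 1.99 ± 3.17 CPM (SD, n = 47) in other IL lines. Solyc07g045080 rose by 6.71 ± 0.50 (edgeR adjusted p = 1.37e-15) through IL7-4 and IL7-4-1, at 2604.7 and 2247.4 CPM, while the other 4 lines of the group stayed at or below 36 CPM.

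GPAT6 (Solyc09g014350), an acyltransferase of cutin synthesis, was the only list member called on its labelled chromosome. It rose by 4.19 ± 0.52 (log2, SE; edgeR adjusted p = 1.68e-07), from 3.69 ± 4.37 CPM (SD, n = 44) in other IL lines to 57.8 ± 81.7 CPM (n = 7) in the chromosome 9 group. The rise lay in IL9-1-3, IL9-2 and IL9-3, at 217.5, 97.9 and 80.8 CPM, and the other 4 lines of the group stayed at or below 7.04 CPM. It held with each line left out and with lyc and ind counts summed (3.93, edgeR adjusted p = 4.99e-07). On chromosome 4 the named gene rose by 4.233 (log2), less than another gene (5.762). The named gene reached 275.3 CPM in IL4-2 and 196.2 CPM in IL4-3, against 6.32 ± 6.12 CPM (n = 47) in other IL lines.

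**Figure D3:**
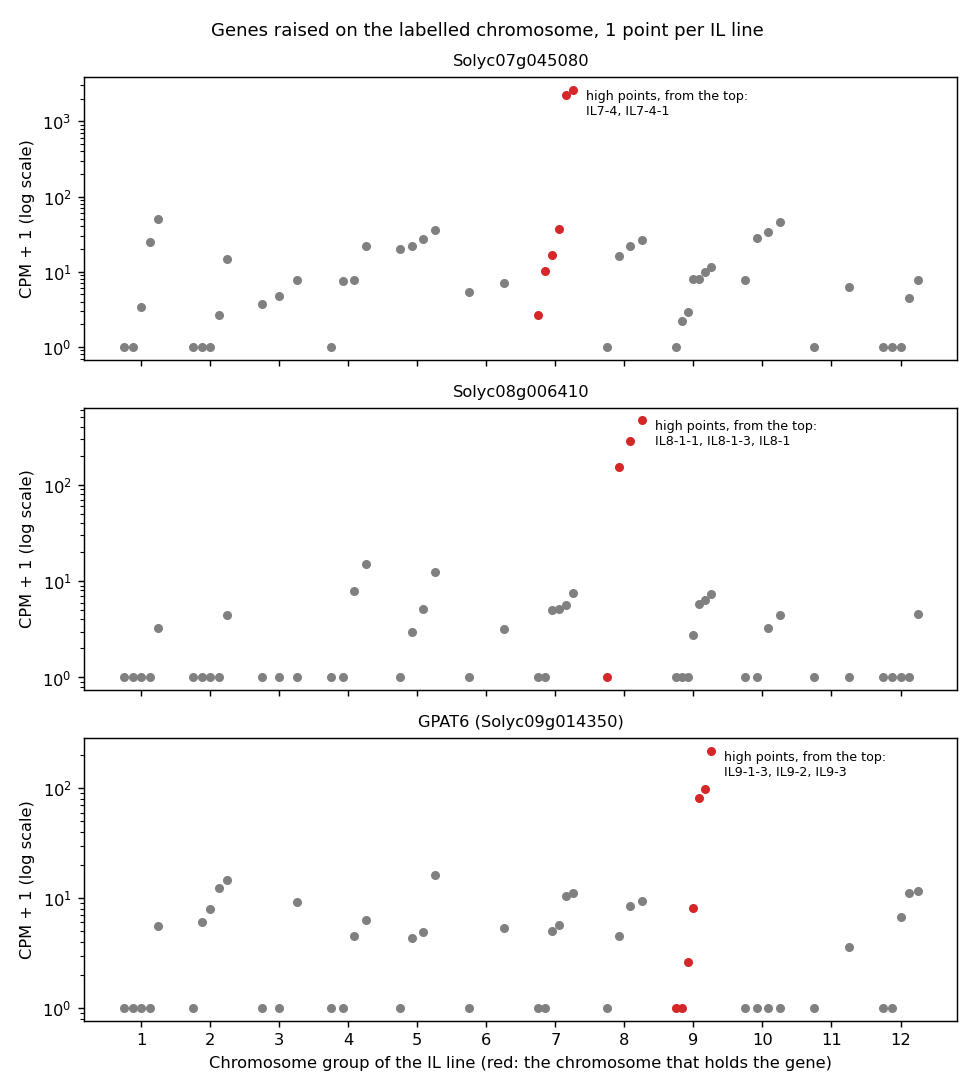
CPM + 1 on a log axis for 3 genes that rose on the labelled chromosome, 1 point per IL line with at least 100000 counts, ordered by value within each chromosome group and red in the group of the gene's own chromosome. For Solyc07g045080, Solyc08g006410 and GPAT6 the high points are 2, 3 and 3 lines of the group, and the others of that group lie among the remaining lines.

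Over the 12 groups together, calls were denser on the labelled chromosome than elsewhere. They made up 0.882% of tests on it and 0.347% off it (Fisher's exact test over genes, which are not independent, p = 7e-11), and without the chromosome 9 group 0.57% and 0.067% (p = 1.64e-21). By group, this passed in chromosomes 1, 2, 3, 4, 6, 7, 8 and 10 (adjusted p of at most 0.0248). It did not pass in 9 (4.78% on and 3.398% off, adjusted p = 0.112), 11 (0.23), 5 (1) or 12 (1), and in chromosome 12 the share was 0.19% on and 0.244% off. By group the labelled chromosome gave 5, 3, 3, 6, 0, 4, 11, 8, 29, 2, 1 and 1 calls for chromosomes 1 to 12. With 1 line left out these counts moved by over 1.5 times in each group. They became 1 without IL1-3, 2 without IL1-4, 1 without IL2-4 or IL2-5, 0 without IL3-3, 2 without IL4-2, 3 without IL4-3, 3 without IL5-3, 1 without IL5-5 and 1 without IL6-3. They became 4 without IL7-4, 7 without IL7-5, 2 without IL8-1-1, 5 without IL8-1-3, and 10, 14, 18 and 19 without IL9-1-3, IL9-2, IL9-3-1 and IL9-3. They became 0 without IL10-2, IL10-3, IL11-4-1, IL12-1 or IL12-1-1, and 2 without IL12-4-1. In the chromosome 5 group edgeR called 0 genes on it and 0 elsewhere, and DESeq2 called 0 and 2. The direction depended on the counts used: with lyc and ind counts summed, 0.32% of tests on the labelled chromosome were rises and 1.45% falls, and 28 of the 73 genes still rose. That sum leaves out pen counts, so a fall in it need not be a fall of expression. With no filter on low counts 3.04% of tests on and 2.1% off the labelled chromosome were called, and by DESeq2 0.326% and 0.118%. Without IL6-2-2, which leaves 1 line in its group, these were 1.29% and 0.509%.

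Away from the labelled chromosome 0.34% of tests were rises and 0.00765% falls, the latter 7 genes, and 82.4% of these calls belonged to the chromosome 9 group. In that group 3.32% of the 7710 tests off chromosome 9 were rises and 0.0778% falls. There RBCS2A (Solyc03g034220), a small subunit of Rubisco, rose by 1.49 ± 0.36 (log2, SE; edgeR adjusted p = 0.0107). GGPPS2 (Solyc04g079960), which makes the precursor of carotenoids, rose by 1.67 ± 0.36 (edgeR adjusted p = 0.00429) and BCAT1 (Solyc12g088220), a branched-chain aminotransferase, by 1.45 ± 0.36 (edgeR adjusted p = 0.0132). With lyc and ind counts summed RBCS2A passed (1.29, edgeR adjusted p = 0.0262), while GGPPS2 (0.905, 0.0631) and BCAT1 (0.711, 0.155) did not. Of the calls off chromosome 9 in this group 41.2% were shared with summed counts. Without lines under 100000 counts or against their label as well, 4.58% were. Adjusted over the list alone, 5 of 8 photosynthesis members rose, and so did the housekeeping genes UBI3 by 0.46 and GAPDH by 0.84. The photosynthesis list as a whole was not called in this group (camera adjusted p = 0.152; adjusted p = 0.753 with an estimated correlation). This group also had the deepest libraries. The number of calls depended on single lines. Without IL9-1-3 the calls off chromosome 9 numbered 4 (0.0521% of tests), while RBCS2A, GGPPS2 and BCAT1 stood at 1.08, 1.46 and 1.09 (adjusted p = 0.284, 0.0987 and 0.277). The mean z-score of the genes that rose there, relative to BIL lines, was 1.753 in IL9-1-3, 1.048 in IL9-2, 1.055 in IL9-3, 1.052 in IL9-3-1 (a line against its label), 0.454 in IL9-2-5, 0.291 in IL9-3-2 and -0.282 in IL9-1, against -0.129 ± 0.405 (SD, n = 44) in other IL lines. Without IL9-3-1, IL9-2 or IL9-3 they made up 1.4%, 1.73% and 1.85%, and BCAT1 was also lost without IL9-2 (0.0659) or IL9-3-1 (0.0525). Over all groups the calls elsewhere made up 0.0669% of tests without IL9-1-3, 0.179% without IL9-3-1, 0.204% without IL9-2 and 0.215% without IL9-3.

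By camera at the preset correlation the flavonoid list stood higher in the groups of chromosomes 3, 7 and 12 and lower in those of 1, 6 and 8, and with an estimated correlation in none. In the chromosome 7 group 4 of 9 flavonoid members rose adjusted over the list alone, among them CHS1 (Solyc09g091510, chalcone synthase) by 1.16 ± 0.37 (log2, SE) and FLS (Solyc11g013110, flavonol synthase) by 0.76 ± 0.23, and over all genes tested 0 did. The list median was 0.52 (camera adjusted p = 4.1e-05; adjusted p = 0.254 with an estimated correlation). In the chromosome 8 group 2 of 9 fell over the list alone, F3H (Solyc02g083860) by -0.79 ± 0.29 and FLS by -0.96 ± 0.34, with 0 over all genes. That list median was -0.65 (camera adjusted p = 4.1e-05; adjusted p = 0.254 with an estimated correlation). In chromosomes 3, 12, 1 and 6 the median was 0.57, 0.54, -0.33 and -0.68 (camera adjusted p = 0.0103, 0.0145, 0.0304 and 0.0023; adjusted p from 0.425 to 0.604 with an estimated correlation), and the chromosome 1 call was lost without lines under 100000 counts (adjusted p = 0.103).

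By camera at the preset correlation the ripening list, which holds ethylene, cell wall and regulator genes, was lower in 3 groups. Its median was -0.42 in chromosome 5 (camera adjusted p = 3.27e-06), -0.54 in chromosome 11 (0.000137) and -0.16 in chromosome 12 (0.000547), and it was 0.35 in chromosome 2 (0.00105). With an estimated correlation the adjusted p was 0.254 for chromosome 5 and 0.425 for the other 3, and 0 of 21 members was called singly in these groups. The photosynthesis list stood the other way in 2 of the 3, with a median of 0.53 in chromosome 5 and 0.57 in chromosome 12 (camera adjusted p = 0.0307 and 0.126), and at 0.01 in chromosome 11. Carotenoid genes stood higher in chromosome 2 (median 0.34, camera adjusted p = 0.0023; adjusted p = 0.425 with an estimated correlation), where ZDS (Solyc01g097810) rose by 1.04 ± 0.26 over the list alone. They stood lower in chromosome 10 (median -0.45, 0.0191; adjusted p = 0.599 with an estimated correlation).

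Photosynthesis genes, markers of green tissue, rose over the list alone in 4 of 8 members in chromosome 5, RBCS1, PSAD, CAB7 and CAB8 (camera adjusted p = 0.0307; adjusted p = 0.72 with an estimated correlation). In chromosome 12 3 of 8 rose over the list alone, and CAB13 (Solyc07g063600), a chlorophyll-binding protein, rose by 3.69 ± 0.79 over all genes (edgeR adjusted p = 0.0164; 0.49 without IL12-4 and 0.0505 without IL12-3-1). In chromosome 6 the list stood lower (median -0.84, camera adjusted p = 0.035; adjusted p = 0.72 with an estimated correlation). The chitinases CHI3 and CHI9 of the defense list rose in chromosome 4 by 1.29 ± 0.43 and 1.15 ± 0.50 over the list alone. Volatile, sugar and acid genes were lower in chromosome 5 (median -0.57, camera adjusted p = 0.00658; adjusted p = 0.347 with an estimated correlation). Of the glycoalkaloid list only GAME7 was measurable, at -0.86 ± 0.42 in chromosome 9 (adjusted p over the list alone = 0.044). The cuticle and housekeeping lists had no camera call, and the defense and glycoalkaloid lists were too small for it. Without lines under 100000 counts camera also called photosynthesis in chromosome 1 (adjusted p = 0.037) and carotenoid in chromosome 9 (0.0492). In all, 19 of 91 list tests were called by camera, 2 with an estimated correlation and 2 by fry.

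IL and BIL skins differed in few genes. In IL lines 8 genes were higher and 13 lower among 6937 tested (edgeR), and 541 had an unadjusted p under 0.05. Of the 13 lower genes 5 lay on chromosome 11, which holds 6.83% of the genes tested (Fisher's exact test over genes, p = 0.00118). Solyc11g012360 stood at 8.18 ± 7.03 CPM (SD, n = 51) in IL and 39.2 ± 91.8 CPM in BIL lines, a log2 fold change of -2.19 ± 0.40 (SE; edgeR adjusted p = 0.000169; 0.0532 with lyc and ind counts summed). Solyc11g062130 fell by 2.09 ± 0.37 on the log2 scale (edgeR adjusted p = 0.000111), and with lyc and ind counts summed it stood at 0.02. Solyc07g045080, the gene of IL7-4 and IL7-4-1, was higher by 1.66 ± 0.31 (edgeR adjusted p = 0.000186). The number of genes moved with the setting, to 497 with no filter on low counts, 81 with lyc and ind counts summed, 36 without the lines in doubt and 8 at an absolute log2 fold change of at least 1.

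Carotenoid and volatile genes were slightly lower in IL lines. The carotenoid list had a median log2 fold change of -0.14 (camera adjusted p = 0.000112; adjusted p = 0.0363 with an estimated correlation), and 2 of 15 members fell over the list alone: PDS (Solyc03g123760, phytoene desaturase) by -0.24 ± 0.08 and HDR (Solyc01g109300) by -0.24 ± 0.09. The volatile, sugar and acid list had a median of -0.21 (camera adjusted p = 0.00026; adjusted p = 0.0363 with an estimated correlation), with 3 of 6 members lower over the list alone, among them LOXC (Solyc01g006540), a lipoxygenase of green-leaf volatiles. The ripening list had a median of -0.12 (camera adjusted p = 0.00026; adjusted p = 0.215 with an estimated correlation), and CEL2 (Solyc09g010210), a cell wall glucanase, fell by 0.66 over the list alone. The flavonoid median was -0.10 (0.0287; adjusted p = 0.307 with an estimated correlation). Over all genes 0 list members passed, and the other lists had no call. Without the lines under 100000 counts the carotenoid and volatile lists had an adjusted p of 0.0691 each with an estimated correlation.

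In ind counts expression strayed slightly more on the labelled chromosome than elsewhere. The median absolute deviation was 0.688 ± 0.629 log2 units (SD, n = 54) on it and 0.659 ± 0.626 on the others. The difference was 0.029 ± 0.044 and was positive in 41 of 54 lines (sign-flip permutation test, p = 2e-05). It had no common direction, as the signed difference was -0.005 ± 0.052 (permutation p = 0.509). Without lines under 100000 counts the deviation was 0.543 ± 0.109 on the labelled chromosome and 0.514 ± 0.101 on the others (n = 51), with a difference of 0.029. A move of reads into or out of the ind table could give such a difference too, and was not tested. With lyc and ind counts summed the signed difference was -0.163 ± 0.142 and negative in 53 of 54 lines (permutation p = 1e-05). That sum leaves out pen counts, which made up 20.64% of species-assigned counts on the labelled chromosome and 2.72% on the others. A negative value can come from this counting alone, so it gives no direction of expression.

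Over BIL lines the comparison asked whether a regulator and its pathway varied together. NOR (Solyc10g006880), a NAC transcription factor of ripening, tracked the ripening list with Pearson's r = 0.577 and Spearman's rho = 0.51 (all BIL lines, permutation p = 1e-05 and adjusted p = 2e-05 for both). Without the 2 farthest lines r was 0.303. MYB12 (Solyc01g079620), a MYB factor of flavonol synthesis, tracked the flavonoid list with r = 0.455 and rho = 0.325 (permutation p = 1e-05, adjusted p = 2e-05). Without the 2 farthest lines r was 0.443. Among the lines with at least 100000 counts, NOR tracked the ripening list more closely than 99.4% of random genes of like level, and MYB12 the flavonoid list more closely than 99.8%.

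RIN (Solyc05g012020), a MADS-box factor of ripening, had r = 0.178 and rho = 0.137 (permutation p = 6e-05 and 0.00398, adjusted p = 8e-05 and 0.00531). After removal of the trend with total count its r was 0.097 (adjusted p = 0.0553), and without lines under 100000 counts 0.071 (adjusted p = 0.14). Without the 2 farthest lines r was 0.179. CD2 (Solyc01g091630), a homeodomain factor of the cuticle, had r = 0.133 and rho = -0.093 with the cuticle list (permutation p = 0.0056 and 0.0523, the same after adjustment). The relation rested on the 2 farthest lines, without which r was 0.049, and it turned to -0.153 without lines under 100000 counts. With lyc and ind counts summed r was 0.519 over all BIL lines and 0.158 without lines under 100000 counts. After removal of the trend with total count r was 0.513 for NOR, 0.357 for MYB12 and -0.074 for CD2. Among the lines with at least 100000 counts, RIN stood above 88.9% of random genes of like level and CD2 above 15.3%, each for its own list. Of 6 planned relations 4 were tested, since GAME9 had a count in 0 and GLK2 in 28 BIL lines.

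**Figure D4:**
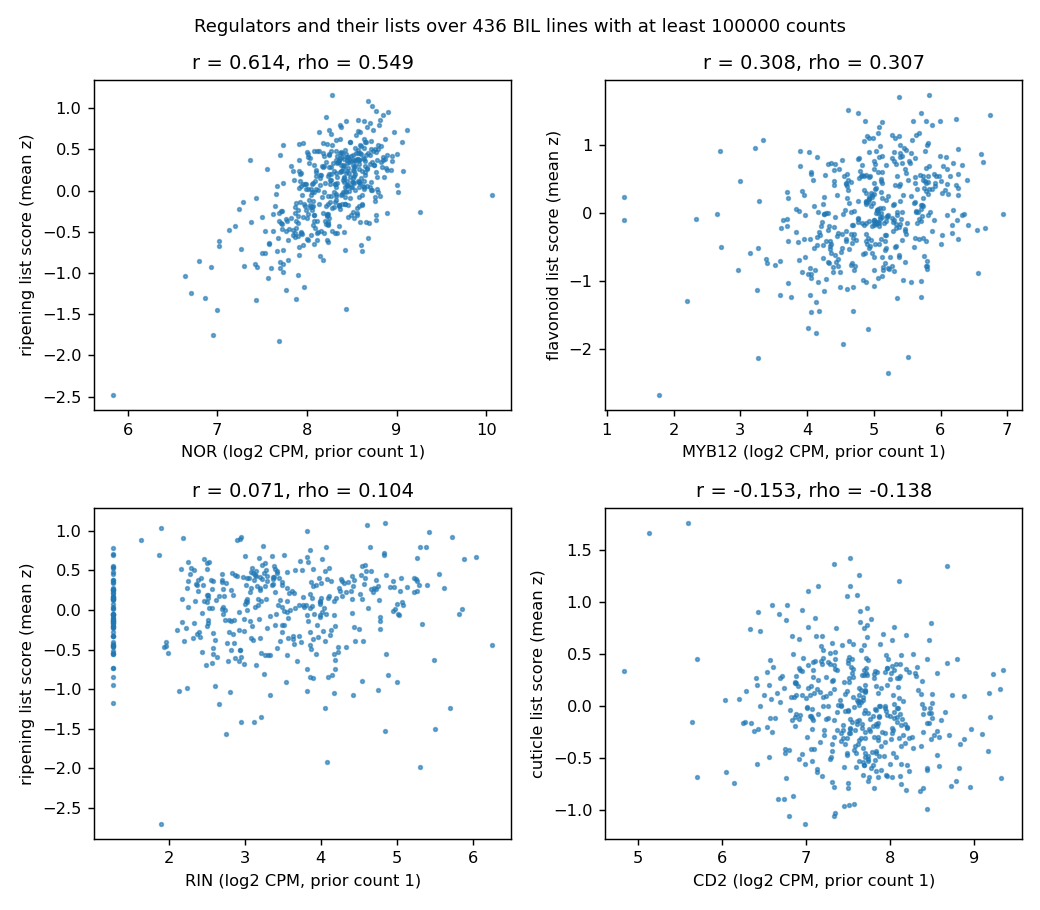
Score of the target list (mean z) against log2 CPM of 4 regulators, 1 point per BIL line with at least 100000 counts. NOR (r = 0.614) and MYB12 (r = 0.308) rise with their lists, RIN (r = 0.071, at a mean of only 10.7 CPM) and CD2 (r = -0.153) hardly do or run the other way.

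Expression repeated weakly between the 2 libraries of a line. Over 26 pairs the median intraclass correlation of 6937 genes was 0.244, and 0 genes were called (2441 at an unadjusted permutation p under 0.05), while 7.25% were called in the 23 BIL pairs alone. By list, over the 26 pairs, it was 0.377 for photosynthesis, 0.342 for cuticle, 0.316 for the single glycoalkaloid gene, 0.276 for carotenoid, 0.238 for volatile, 0.112 for flavonoid, 0.091 for ripening and for housekeeping, and 0.009 for defense, and 4 of 6 photosynthesis, 1 of 6 volatile and 1 of 5 housekeeping genes were called over the list alone. In the 21 pairs with at least 50000 ind and lyc counts per library the median over genes was 0.053 and 0 genes were called (665 at an unadjusted permutation p under 0.05 and 1091 in the lyc table). By list, in these deep pairs, it was 0.212 for cuticle, 0.188 for photosynthesis, 0.096 for volatile, 0.046 for ripening, 0.038 for carotenoid, 0.032 for housekeeping, 0.007 for glycoalkaloid, -0.053 for defense and -0.056 for flavonoid. Of the 25 pairs compared, 0 held identical counts.

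The wild read profiles over chromosomes matched in 14 of the 21 deep pairs, with a correlation of at least 0.94. They did not match in 7 pairs, lines 6180, 6220, 6222, 6383, 6585, 6676 and IL2-3, with correlations from -0.28 to 0.24. Of 10000 random pairs of lines 2.41% passed 0.9.

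**Figure D5:**
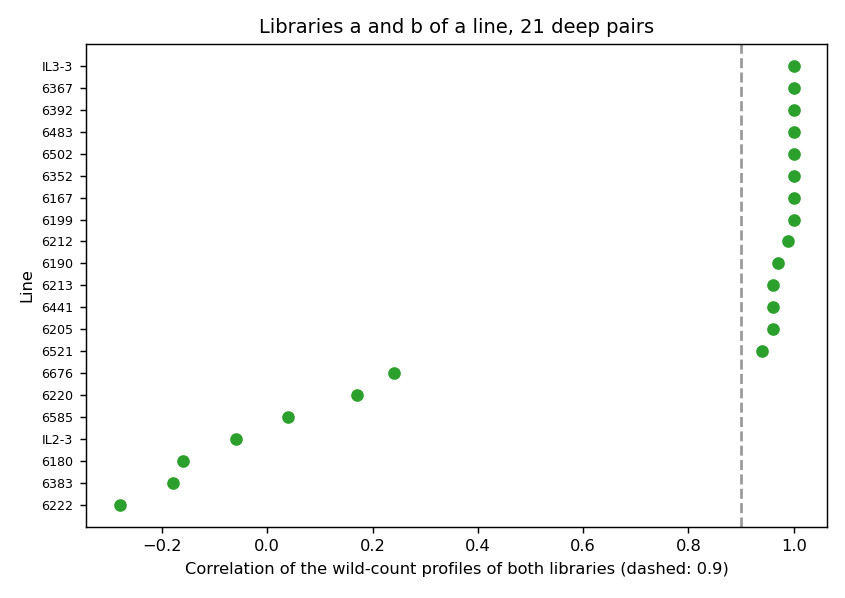
Correlation of the wild-count profiles of libraries a and b (horizontal axis) for each of the 21 lines with deep libraries (vertical axis), with the limit of 0.9 dashed. In 14 pairs the correlation is 0.94 or more, and in 7 it is 0.24 or less.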

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

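The random groupings and their adjustment, the summed counts, the spread used to judge depth, the line left out and the label tests were chosen only after the result was seen, and the tests of wild segments and depth over BIL lines were set before it.

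A single line made the rise of the named gene in 2 groups. On chromosome 1 that gene rose by 4.655 (log2), less than another gene (5.839). The named gene stood at 1177 CPM in IL1-3 and between 0.0 and 19.2 CPM in the other 4 lines of its group. Without IL1-3 its log2 fold change was 0.42. On chromosome 2 the named gene rose by 1.913, less than another gene (2.521). The named gene stood at 1013 CPM in IL2-3, against 34.5 to 82.3 CPM in the other 4. Its log2 fold change was -0.17 without IL2-3, a line whose libraries differ in their wild reads. These were the samples far from the others in 2 of 48 groups tested, and chance gives about 1 in 20. No explanation was tested.

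On the labelled chromosome ind counts gave rises alone, while in summed lyc and ind counts falls (1.45% of tests) outnumbered rises (0.32%). Away from it, rises in ind counts also far outnumbered falls (0.34% and 0.00765% of tests). An excess of rises is thus not particular to the labelled chromosome. The simulations counted rises and falls together, so the power to find falls is not known. Random groupings of the lines gave as many calls as the real 73 in 1 of 100, the real grouping, and the highest of the others was 54, so chance is excluded. Over BIL lines with at least 100000 counts the median rank correlation of these genes with the wild share of their own chromosome was 0.088. The correlation was positive in 61 of 73, and the median had a one-sided permutation p = 0.0001, the smallest possible. With every gene set against another chromosome by the same shift in chromosome number, the highest median over all shifts was 0.027. The wild segment itself may therefore raise these genes. A move of reads between the lyc and ind tables leaves their sum as it is and is excluded for the 28 genes whose sum rose too, while a move out of the pen table stays open. For the other 45 the wild segment and a move of reads cannot be told apart, because reads of a wild allele also leave for the pen table, whose loci are not paired with these.

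The calls off chromosome 9 in the chromosome 9 group, 3.4% of tests and 97.7% of them rises, depended on single lines: without IL9-1-3 there were 4 (0.0521%), without IL9-3-1, IL9-2 or IL9-3 1.4%, 1.73% and 1.85%, and without another line up to 4.65% (IL9-1), and 21.8% of them were shared without the lines under 100000 counts or against their label, IL9-3-1 among the latter. Whether 1 line made them stays open, since the score of these genes was 1.753 in IL9-1-3, 1.048, 1.055 and 1.052 in IL9-2, IL9-3 and IL9-3-1, 0.454 and 0.291 in IL9-2-5 and IL9-3-2 and -0.282 in IL9-1, and the genes were chosen from the same lines. Random groupings gave as many in 2 of 100, with 1.6 times the real count in the highest of the others. Chance is therefore excluded for this test taken singly, and not after adjustment over the 24 tests of this kind (adjusted share 0.12). For that adjustment 100 groupings are too few to decide. Depth predicted 18.8% of the group's excess in this score (14.6% to 26.3% within 1 SE), 0.767 ± 0.663 (SD, n = 7) against -0.129 ± 0.405 (n = 44), and stays open, because choosing the genes in these lines raises the excess. The wild segment of chromosome 9 stays open, with a median rank correlation of 0.078 over BIL lines and 0.13 with another chromosome.

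In 5 IL lines with at least 100000 counts the highest excess of wild reads lay on a chromosome other than the labelled one, by 0.25 percentage points over background in IL5-2 and by over 2 in the other 4. A swap of 2 whole IL lines with at least 100000 counts is excluded, since 0 of these 4 had a partner out of place. Swaps with lines of fewer counts, with BIL lines or of single libraries were not searched. In IL3-4 and IL12-4-1 the highest excess on the labelled chromosome was -0.03 percentage points, so no wild reads above background were seen there. This does not exclude a mixture with the labelled line, because a named segment can give a small excess. It was 1.34 points in IL4-1-1 and 1.99 in IL11-4-1, whose highest excess lay on the labelled chromosome. For the 2 lines with an excess on both, IL2-4 and IL9-3-1, a mixture and a second wild segment cannot be told apart, because both give wild reads on 2 chromosomes. A wrong label or a wild segment other than the named one stays open for all 4, as untested.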

How the results depend on the processing

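The fits without lines under 100000 counts, without lines against their label (with IL2-3), on the lyc table, on deep or matching pairs, of the signed deviation and of summed counts in the relations, the deviation or with fewer lines were chosen only after the result was seen. No paired analysis was possible because no line was measured under 2 conditions. Shares per gene and the sum of the 3 tables were not run, since loci are not paired. The differences in wild read share kept their direction and side of the threshold under each alternative run, of which the one without lines whose highest excess lay elsewhere tells nothing, since these lines were chosen by the same shares. Of the named genes, 74.1% of values in IL groups and 91.5% between IL and BIL stayed the same, 89 and 11 lost the threshold and 6 and 2 reversed.

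IL against BIL gave 497 genes with no filter on low counts, where more genes were tested, 81 with lyc and ind counts summed, 36 without lines under 100000 counts or against their label and 8 at an absolute log2 fold change of at least 1. With summed counts Solyc11g062130 stood at 0.02 and the chromosome 1 gene that was higher by 0.78 at -0.12.

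On the labelled chromosome 3.04% of tests were called with no filter, 0.568% with the other IL lines as 1 group and 0.326% by DESeq2. With lyc and ind counts summed 1.77% were called, 1.45% as falls, and without the lines in doubt 1.54%, 1.32% as falls. Both sums leave out pen counts, so these falls need not be falls of expression. The direction reversed in groups 4, 6, 8, 9 and 11 (19, 88, 58, 47 and 1 calls), and without the lines in doubt in groups 2, 4, 6, 8, 9 and 11 (1, 19, 84, 55, 21 and 2). Elsewhere 0.144% of tests were called with adjustment over all contrasts together, 2.1% with no filter, 0.34% with summed counts (a higher count among more tests), 0.0951% with the other lines as 1 group, 0.11% without the lines in doubt, 0.114% with both and 0.118% by DESeq2. With each line left out, calls ran from 0.667% to 1.29% on the labelled chromosome and from 0.0669% to 0.509% elsewhere. The highest came without IL6-2-2, where the lone chromosome 6 line is assumed to vary like the other groups. The fit without IL6-3 also leaves a lone chromosome 6 line. Elsewhere calls made up 0.0669%, 0.179%, 0.204% and 0.215% without IL9-1-3, IL9-3-1, IL9-2 and IL9-3.

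The named rise elsewhere in the chromosome 1 group stood at -0.12 without the 6 lines of lowest total. With a line left out it ran from -0.09 (without IL1-1) to 2.49. The named rise on chromosome 2 stood at -0.18 without the lines in doubt and at -0.12 with summed counts as well. With a line left out it ran from -0.17 (without IL2-3) to 2.23. The named rise elsewhere in the chromosome 6 group ran from -0.14 (without IL6-3) to 4.59.

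The signed deviation was -0.163 with summed counts, which leave out pen counts and so give no direction of expression. The median intraclass correlation was 0.053 in deep pairs, 0.065 in those with matching profiles and 0.104 in deep pairs of the lyc table, and BIL pairs alone gave 7.25% of genes. After removal of the trend with total count 2 relations passed. RIN fell to 0.097, and to 0.071 without lines under 100000 counts. Without these lines it stood at 0.195 with summed counts and at 0.198 in the lyc table. CD2 had r = -0.074 after that removal, 0.049 without the 2 farthest lines (rho = -0.107) and -0.153 without lines under 100000 counts (rho = -0.138). Its rho was 0.149 with summed counts, 0.13 with these and without the low lines, and 0.225 in the lyc table without them. List calls numbered 2 with an estimated correlation, 2 by fry and 0 with an estimated correlation without lines under 100000 counts. Except where fewer or more genes or lines were tested, the cause was not tested. The number of lines limits small groups, as simulated 2-fold changes were recovered in 6% of genes at 2 lines and 34% at 7, and the simulation did not vary depth.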

Other observations

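The random groupings and their adjustment, the lyc table in matching pairs and the spread used to judge these pairs were chosen only after the result was seen, and the tests of chromosome 11 and of matching pairs were set before it.

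Wild chromosome 11 may lie behind part of the difference between IL and BIL skins. The 5 chromosome 11 genes that were lower in IL lines had a median rank correlation of 0.278 with the wild share of chromosome 11 over BIL lines with at least 100000 counts, positive in 5 of 5 and at most 0.147 with another chromosome (one-sided permutation p = 0.0001, the smallest possible). With lyc and ind counts summed 2 of the 5 stayed lower past the threshold. For the other 3 (adjusted p = 0.0532, 0.0934 and 0.998) a move of reads between the tables would give the same correlation and stays open. Chromosome 11 is also where BIL lines carried the most wild reads, 13% on average. This is a hypothesis, since genes and test share the BIL lines. For the whole count of 21 genes chance is not excluded: 2 of 40 splits gave as many, the real one included, and the highest of the others was 25.

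The calls of each chromosome group were set against random groupings in 24 tests. With adjustment over these tests none passed (lowest adjusted share 0.12), but 100 groupings are too few for that adjustment to decide. The smallest possible share is 1 of 100, and a single test at that share could not pass over 24 tests. Each test taken singly, at under 5 of 100, chance is excluded for the calls on the labelled chromosome in groups 2, 4, 6, 7, 8 and 9. Random groupings gave as many as the real 3, 6, 4, 11, 8 and 29 in 4, 4, 4, 1, 1 and 2 of 100, with 11, 9, 35, 4, 7 and 49 in the highest of the others. It is not excluded in groups 1, 3, 5, 10, 11 and 12, with as many as the real 5, 3, 0, 2, 1 and 1 in 5, 6, 100, 6, 32 and 26 of 100 and 6, 6, 7, 6, 21 and 9 in the highest. Away from the labelled chromosome it is excluded, taken singly, in group 12 (real 19, as many in 4, highest of the others 70; 4 calls without IL12-1 or IL12-1-1 and 38 without IL12-4-1) and in group 9 (real 3.4% of tests, as many in 2, highest 1.6 times the real count). It is not excluded in groups 1, 2, 3, 4, 5, 6, 7, 8, 10 and 11, with as many as the real 2, 3, 1, 4, 0, 6, 5, 14, 0 and 2 in 74, 58, 74, 56, 100, 34, 40, 13, 100 and 74 of 100. The highest of the others there ran from 27 calls in group 3 to 160 in group 4, with more than that in groups 6 and 11, several times the real counts. Single lines or a structure among the lines may give such calls, and the cause was not tested. They were 47, 99, 53, 55 and 74 in groups 1, 2, 5, 7 and 10, 7.71 times the real count in group 8 and 51 times in group 6, which holds 2 lines. Over all groups, 3 of 100 groupings gave as many calls as the real one, and the highest of the others had 1.31 times its count.

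Whether mixed pairs lie behind the low repeatability in deep libraries stays open. In the 14 pairs with matching wild read profiles the median intraclass correlation was 0.065 in the ind table and 0.132 in the lyc table. In all 21 deep pairs it was 0.053 and 0.104. The spread of the median over the 14 pairs was not computed. The bootstrap SD of 0.137 is over all 26 pairs, those of low depth included, so it cannot decide. In line 6180 library a had 80.21% wild reads on chromosome 11 and library b 38.47% on chromosome 3. The order of the a and b columns differed between the tables in 11 of 26 pairs. In these 11 the difference between a and b in the ind table ran against that in the lyc table, and in the other 15 it ran with it (Fisher's exact test, p = 1.3e-07). Columns were joined by name, and counts summed per line do not depend on it. Totals of single libraries over the 3 tables do. In line 6223 library a held 1615 ind and 1246058 lyc counts, and library b 561521 ind and 3800 lyc counts.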
